A study of Arabidopsis thaliana with 11 samples.

How the data were processed

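Strand-specific mRNA libraries from whole Arabidopsis thaliana seedlings, 10 days old and untreated, were sequenced for 4 genotypes. These were wild type of the accession Col-0 (n = 3), the xpo4-2 mutant (n = 2), the cpr5 mutant (n = 3) and the xpo4-2 cpr5 double mutant (n = 3). Group and replicate number were taken from the sample titles. The labels do not say that the replicates came from separate plates or sowings, so p-values measure only the spread between these samples, which may be technical. The design text speaks of 3 samples per genotype, and 2 xpo4-2 libraries were analysed here.

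The deposited count table holds whole numbers for 22160 genes in 11 libraries, with no line that names no gene. Per the submitters' processing notes, HISAT2 2.0.4, HTSeq 0.6.1p1 and the TAIR10 genome were used, without the role of each. The deposited TPM table holds 71164 transcripts, of which 17151 are assembled models not tied to a gene, and its deposited name credits kallisto, with no version. The count values followed that table closely. Log2 of count over TPM was taken for 5998 genes with 1 listed transcript and at least 100 counts in every library. Its standard deviation within genes was 0.0146, against 0.0656 from sampling noise alone between independent samples. Of 7411 combinations of gene and library at 0 counts, 0 had a TPM of at least 1. Both tables come from the same libraries, so sampling noise is shared and such a small value does not tell which tool made the counts. The deposited values were treated, as an assumption, as estimated counts rounded to whole numbers, and the test planned for counts was kept. Either way, TPM is no independent measurement of the same libraries. Every gene listed had at least 5 counts in at least 2 libraries, so a filter had been applied before deposit, and its rule is not given in the sources used here.

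Neither a strand setting nor the treatment of reads that match several genes is given in the sources used here. Values of near-identical genes are therefore uncertain as to the single copy, which applies to the small subunits of Rubisco, the LHCB1 and LHCB2 genes, VSP1 and VSP2, BIP1 and BIP2, and the glutathione transferases. The same holds for genes that overlap another gene on either strand. For 44 genes the counts equalled those of another gene in every library.

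Library totals ran from 16922732 to 23088104 counts. Estimated counts of reads without molecular identifiers are not independent molecules, and floors cover counting error only. Intervals are over libraries for marker lists and over genes, which are not independent, for shares of genes. A group with every library at 0 was set to a floor of 3 counts over its libraries together, and folds against it are given as lower bounds. Such a bound does not hold where the quantification gave the reads of a gene to another transcript. Names were taken from the reference gene table of the TAIR10.1 assembly, in which 22011 of the genes matched an entry. That table has no symbol for XPO4, whose locus AT3G04490 it describes as exportin-4.

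Differential abundance was tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr by group, which kept 21580 and removed 580, and libraries were scaled with TMM factors. The quasi-likelihood test (glmQLFit and glmQLFTest) was run in 1 fit of all 11 libraries with a term per group, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05 with no fold threshold. The common dispersion was 0.093, a biological coefficient of variation of 0.305. Standard errors (SE) of log2 fold changes were taken from the fold change and its F statistic. The 6 comparisons were xpo4-2, cpr5 and xpo4-2 cpr5 each against wild type, the double mutant against cpr5 and against xpo4-2, and the interaction, which is the effect of xpo4-2 in cpr5 minus its effect in wild type.

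The groups, comparisons, their tests, the gene lists, the rule for named genes and the alternatives were chosen before the data were examined. The 23 lists covered SA-responsive defence genes (SA, salicylic acid), SA biosynthesis and signalling, the N-hydroxypipecolic acid pathway, pattern-triggered immunity, NLR immune receptors, camalexin and indole metabolism, jasmonate and ethylene response, senescence, photosynthesis, the mitotic cell cycle, SIM/SMR cell cycle inhibitors, nuclear transport receptors and nucleoporins, TOPLESS corepressors and their DND targets, ER stress, oxidative stress and glutathione transferases, heat shock, abscisic acid and cold response, and anthocyanin and flavonoid. A further 5 held markers of cell types, namely trichome, root and root hair, stomatal lineage, vascular tissue and seed storage. Of 263 members, 259 matched a gene by symbol and 249 were measured. SARD4, NRG1.1, NRG1.2 and CAS were the members without a match. Each list was tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. The fry test, planned for direction, was also run on each list, without adjustment over lists. Members were also adjusted over the list alone.

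The genes named were XPO4 and CPR5, up to 4 members per list and comparison with the lowest adjusted p that passed (or the member with the lowest where none passed), and the 5 largest rises and falls per comparison. The last needed an adjusted p under 0.05, a mean of at least 5 counts in each 1000000 (CPM, scaled with the same factors) in the higher group and, outside the interaction, no overlap between libraries. Since this choice favours genes without overlap, the lack of overlap in a named gene is no further evidence. Where fewer list members are named, they are those with the lowest adjusted p.

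The alternatives were RLE factors, no scaling beyond library size, the DESeq2 1.42.0 Wald test, no low-count filter, at least 1 CPM in 3 or more libraries, only the groups compared, a log2 fold change of at least 1 in absolute value, the replicate number as a block, and limma on log2(TPM + 0.5) or log2(TPM + 0.1), the former also without a filter. Each of the 11 libraries was left out in turn. A group left with 1 library was then assumed to vary like the others. Fold changes on the TPM scale understate those of low genes.

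The procedure was tested on simulated data with the real means, dispersions and library sizes of 21580 genes and 200 changed genes. In the simulation of xpo4-2 against wild type, 54.5% of genes changed 4-fold were recovered, 14.9% at 2-fold and 0% at 1.5-fold, with 0 false calls. For cpr5 against wild type the shares were 59.1%, 25.4% and 1.49%, with 3 false calls, and for xpo4-2 cpr5 against cpr5 they were 66.7%, 13.4% and 2.99%, with 4 false calls. With 200 of 21580 genes changed, most 2-fold and many 4-fold changes were thus missed at this depth and number of libraries. Where more genes change, the adjusted p threshold is less strict, so these shares do not give the power of comparisons with many calls. In the data, 4682 genes passed in xpo4-2 cpr5 against cpr5, of which 754 higher and 1404 lower reached 2-fold. A list raised 2-fold in the simulated double mutant was called at an adjusted p of 6.01e-16 and 0 of the other 22 lists. Genes were drawn independently there, so the simulation cannot show false list calls that arise when members vary together. Limma was run on simulated TPM with the same set spread for every gene in place of the real dispersions. Its changed genes were picked above a TPM threshold. It recovered 100% of 4-fold changes among 20385 genes, with 11 false calls, a share not comparable with those above.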

Results

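Transcripts of whole seedlings, 10 days old, were measured by strand-specific mRNA sequencing in wild type (n = 3), xpo4-2 (n = 2), cpr5 (n = 3) and xpo4-2 cpr5 (n = 3). CPR5 encodes a membrane protein of the nuclear pore, and cpr5 mutants show constitutive salicylic acid (SA) defence. XPO4 encodes exportin-4, a nuclear transport receptor. Total counts were 17871531, 18246148 and 19279951 in wild type, 19834595 and 23088104 in xpo4-2, 19976102, 19938040 and 16922732 in cpr5, and 19254636, 17398977 and 20927373 in the double mutant. A single count equals 0.0433 to 0.0591 CPM before scaling, and between 20880 and 21903 genes had a count per library. Levels below are mean ± SD in CPM, with the number of libraries per group given above.

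The double mutant stood apart from the other genotypes. The first principal component held 42.5% of the variance and the second 11.4%. The double mutant libraries lay at 98.8 to 114 on the first component, the cpr5 libraries at 0.43 to 8.72, and the wild-type libraries at -127, -68.8 and -40.9. The xpo4-2 libraries lay at -65 and -32.1, the latter between wild type and cpr5. Wild type was the most spread group, with correlations of 0.898 to 0.940 between libraries across genes, against 0.964 to 0.974 in cpr5, and wild-type replicate 1 lay farthest out. Genes within a library are not independent replicates. Replicates differed beyond sampling noise in every group, with a lowest chi-square per degree of freedom of 11.7, in cpr5. The 10 most abundant genes took 3.23% to 3.66% of counts in the double mutant and 4.66% to 7.57% in the other libraries. Genes of the plastid genome took 0.300% to 0.439% in wild type, 0.167% and 0.315% in xpo4-2, 0.142% to 0.165% in cpr5 and 0.133% to 0.177% in the double mutant.

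**Figure D1:**
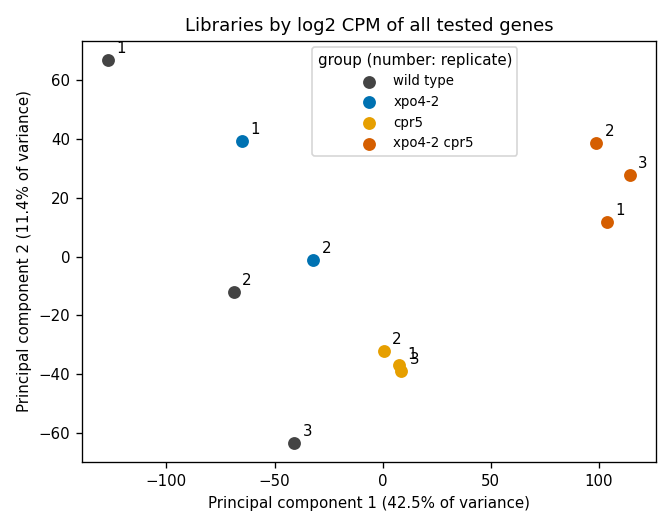
Principal components of log2 CPM over 21580 genes, with PC1 (42.5% of variance) across and PC2 (11.4%) up; each point is a library, coloured by genotype and numbered by replicate. The double mutant libraries lie at 98.8 to 114 on PC1 and the cpr5 libraries at 0.43 to 8.72.

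XPO4 (AT3G04490, chromosome 3, 1200331 to 1209970 in TAIR10.1) stood at 21.5 ± 1.94 CPM in wild type and 23 ± 4.7 in cpr5. Its level was 2.90 ± 2.68 in xpo4-2 and 1.46 ± 1.26 in xpo4-2 cpr5. XPO4 fell 15.5-fold in the double mutant against cpr5 (log2 fold change -3.95, SE 0.819, adjusted p = 0.00715) and 14.5-fold against wild type (adjusted p = 0.00403). In xpo4-2 against wild type the log2 fold change of XPO4 was -2.87 (SE 0.907), and it did not pass (adjusted p = 0.121). That p ran from 0.0294 to 0.393 over the alternatives, and it passed without xpo4-2 cpr5 replicate 2 (0.0294) and with limma on log2(TPM + 0.5), at 0.0308 with the filter and 0.0455 without. CPR5 (AT5G64930, chromosome 5, 25945683 to 25948397) stood at 10.9 ± 2.65 CPM in wild type, 13.4 ± 1.31 in xpo4-2, 16.1 ± 1.5 in cpr5 and 24.0 ± 0.537 in the double mutant. CPR5 rose in the double mutant against wild type (log2 fold change 1.13, SE 0.186, adjusted p = 0.00093), and its log2 fold change in cpr5 against wild type was 0.56 (adjusted p = 0.107). The rise of CPR5 in the double mutant against cpr5 (0.57, adjusted p = 0.0476) was lost without any of 9 libraries, with an adjusted p of up to 0.141 (without cpr5 replicate 3), and with the replicate block (0.0537). Against xpo4-2 it rose by 0.84 (adjusted p = 0.0127, and 0.107 without xpo4-2 replicate 1), while XPO4 had a log2 fold change of -0.99 there (adjusted p = 0.438). Transcript level of CPR5 is therefore no check on which libraries carry the cpr5 mutation.

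**Figure D2:**
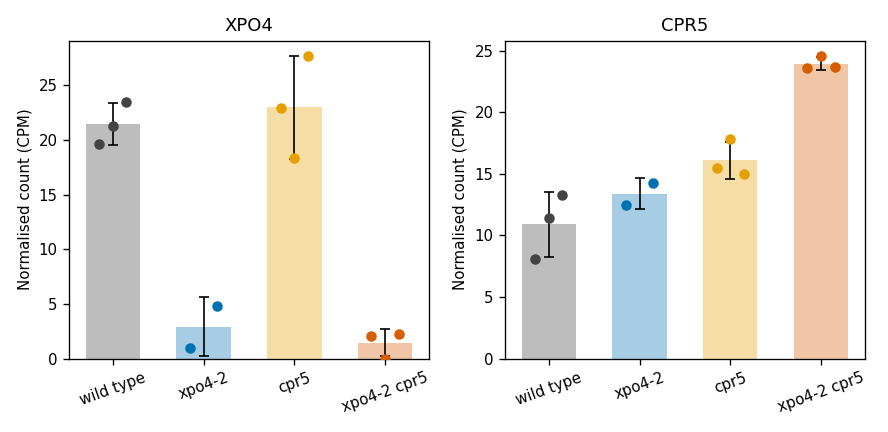
Levels of XPO4 and CPR5 (CPM, linear axis) in the 4 genotypes; bars are means, error bars SD and points libraries (n = 3, or 2 for xpo4-2). XPO4 stands at 23 CPM in cpr5 and 1.46 in xpo4-2 cpr5.

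The comparison of cpr5 with wild type asks what the cpr5 mutation alone changes. SARD1 and CBP60G, transcription factors that switch on SA synthesis, rose 6.37-fold (23.6 ± 4.97 to 150 ± 31.6 CPM; log2 SE 0.201, adjusted p = 0.000187) and 3.82-fold (23.6 ± 6.23 to 90.3 ± 14.4; adjusted p = 0.000945). PBS3, an enzyme of SA synthesis, rose 7.91-fold (adjusted p = 0.00155), and DMR6, an SA hydroxylase, rose 6.13-fold (adjusted p = 0.00064). PR1, the standard marker of SA defence, rose 22.0-fold, from 25.8 ± 20 to 567 ± 197 CPM (log2 SE 0.766, adjusted p = 0.00877). WRKY46, a defence transcription factor, rose 4-fold (adjusted p = 0.00434), and NIMIN1, a partner of the SA receptor NPR1, rose 9.09-fold (adjusted p = 0.00752).

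Of the SA biosynthesis and signalling list, 11 of 15 genes rose and none fell (12 adjusted over the list alone; list adjusted p = 7.54e-25, and adjusted p = 0.0214 with an estimated correlation). Of the SA-responsive defence genes, 10 of 14 rose (13 adjusted over the list alone; list adjusted p = 4.55e-14, and adjusted p = 0.0681 with an estimated correlation). In pattern-triggered immunity 8 of 19 genes rose (10 adjusted over the list alone; list adjusted p = 1.44e-09, and adjusted p = 0.0214 with an estimated correlation). They included CYP81F2, an enzyme of indole glucosinolate metabolism (4.18-fold, 24.0 ± 1.43 to 100 ± 8.42 CPM, adjusted p = 0.000299), the receptor-like kinase SOBIR1 (2.23-fold, adjusted p = 0.00118) and the transcription factor WRKY33 (3.11-fold, adjusted p = 0.00123). Among NLR immune receptors 4 of 15 rose (7 adjusted over the list alone; list adjusted p = 0.000116, and adjusted p = 0.0215 with an estimated correlation), led by the helper NLR ADR1-L2 (1.55-fold, adjusted p = 0.0052). SA biosynthesis and signalling, pattern-triggered immunity and NLR immune receptors in cpr5 were the 3 list calls, over all comparisons, that held with an estimated correlation. In the N-hydroxypipecolic acid pathway, which makes a signal of systemic resistance, 2 of 3 genes rose (3 adjusted over the list alone; list adjusted p = 0.00141, and adjusted p = 0.159 with an estimated correlation). Its FMO1 rose 4-fold (adjusted p = 0.0201), a call lost without any 1 of the cpr5 libraries, with an adjusted p of up to 0.0718 (without cpr5 replicate 3). In senescence 4 of 11 genes rose (5 rose and 1 fell adjusted over the list alone; list adjusted p = 6.33e-05, and adjusted p = 0.121 with an estimated correlation), led by the sugar transporter SAG29 (8.97-fold, adjusted p = 0.00362). Some tissue markers passed as lists in cpr5. Root and root hair had 1 gene higher of 12 (1 adjusted over the list alone; list adjusted p = 0.00879, adjusted p = 0.37 with an estimated correlation, and 0.106 without wild-type replicate 1). Vascular tissue had 0 of 7 (3 higher adjusted over the list alone; list median 0.724, list adjusted p = 0.029, and adjusted p = 0.202 with an estimated correlation), and seed storage 1 lower of 2 (1 adjusted over the list alone; list adjusted p = 0.016, and adjusted p = 0.121 with an estimated correlation). The vascular call was lost without wild-type replicate 3 (0.0909) or cpr5 replicate 2 (0.0614) or 3 (0.0888), with at least 1 CPM in 3 or more libraries (0.0796), with only the groups compared (0.0612) and with limma on log2(TPM + 0.5) (0.066) or log2(TPM + 0.1) (0.0713). The seed storage call was lost without wild-type replicate 3 (0.0722) or cpr5 replicate 2 (0.0614), without a low-count filter (0.0772) and with limma on log2(TPM + 0.1) (0.069) or on log2(TPM + 0.5) without a filter (0.116). None of the 20 photosynthesis genes passed, also adjusted over the list alone (list adjusted p = 0.953), and the jasmonate and ethylene list had 1 gene higher and 1 lower of 18 (1 and 3 adjusted over the list alone; list adjusted p = 0.43).

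Among the 5 largest falls in cpr5, AT3G05170 fell 46.7-fold (8.80 ± 1.98 to 0.180 ± 0.0711 CPM, adjusted p = 3.49e-05). NRT1.7, a nitrate transporter of the phloem, fell 20.4-fold (224 ± 41.1 to 11 ± 0.208 CPM, adjusted p = 0.000101), and IPS1, a non-coding RNA induced by phosphate starvation, fell 23-fold (adjusted p = 0.00318). GGPS6 fell at least 125-fold, and its call was lost without cpr5 replicate 1 (adjusted p = 0.051). CPL2, a phosphatase of RNA polymerase II, was at least 227-fold higher, and AT1G51035 at least 99-fold higher. Neither had a count in any wild-type library, so reads given to another transcript and a difference of genotype cannot be told apart. AT5G63225 rose 47.2-fold (0.133 ± 0.0638 to 6.60 ± 1.45 CPM, adjusted p = 3.49e-05). AT1G75945 stood at 0.02 CPM in wild type and 6.77 in cpr5, and AT3G05950 at 0.0577 and 15.4. In all, 928 genes rose and 505 fell of 21580. Of 46 named genes that passed, 26 did so whichever library was left out. The higher count was 614 without wild-type replicate 2 and 357, 485 and 466 without cpr5 replicates 1, 2 and 3. The lower count was 332, 201 and 826 without wild-type replicates 1, 2 and 3 and 107, 138 and 98 without the cpr5 replicates.

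The comparison of xpo4-2 cpr5 with cpr5 asks what the xpo4-2 mutation changes in the cpr5 background. ICS1, which makes the precursor of SA, rose 7.86-fold, from 47.9 ± 8.48 to 377 ± 59.3 CPM (log2 SE 0.299, adjusted p = 0.000185), and PBS3 rose 6.98-fold, from 48.9 ± 7.8 to 342 ± 61.4 (adjusted p = 0.000463). FMO1, which makes N-hydroxypipecolic acid, rose 12.0-fold, from 14.7 ± 1.84 to 176 ± 29.2 CPM (log2 SE 0.412, adjusted p = 0.000329). All 20 photosynthesis genes fell, among them LHCB3 of the light-harvesting antenna (9.35-fold, 2400 ± 136 to 257 ± 100 CPM, log2 SE 0.324, adjusted p = 0.000185) and the Rubisco small subunit RBCS3B (3.35-fold, 4820 ± 445 to 1440 ± 186, adjusted p = 0.000232). VSP2, a storage protein induced by jasmonate, fell 24.2-fold, from 232 ± 24.1 to 9.59 ± 1.43 CPM (log2 SE 0.301, adjusted p = 4.06e-05).

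In SA biosynthesis and signalling 11 of 15 genes rose and none fell (11 adjusted over the list alone; list adjusted p = 1.13e-09, and adjusted p = 0.144 with an estimated correlation). SARD1 rose 3.02-fold, to 453 ± 37.4 CPM (adjusted p = 0.000409), and CBP60G 2.54-fold, to 230 ± 24 (adjusted p = 0.00118). Of the SA-responsive defence genes 7 of 14 rose (10 adjusted over the list alone; list adjusted p = 0.000165, and adjusted p = 0.314 with an estimated correlation). The transcription factors WRKY46 and WRKY70 rose 2.97-fold (adjusted p = 0.00367) and 2.60-fold (adjusted p = 0.00567), and the glucanase PR2 rose 4.98-fold (adjusted p = 0.0115). PR1 stood at 567 ± 197 CPM in cpr5 and 1840 ± 332 in the double mutant, with a log2 fold change of 1.70 that did not pass (adjusted p = 0.101). In the N-hydroxypipecolic acid pathway 2 of 3 genes rose, FMO1 and UGT76B1, a glucosyltransferase that inactivates the signal (3.64-fold, adjusted p = 0.00702); the list had 3 adjusted over the list alone and an adjusted p of 0.000929 (adjusted p = 0.179 with an estimated correlation). Pattern-triggered immunity had 2 genes higher and 2 lower of 19 (2 and 4 adjusted over the list alone; list adjusted p = 0.947), with the flagellin receptor FLS2 up 2.75-fold (adjusted p = 0.00989). NLR immune receptors had 3 higher and 3 lower of 15 (3 and 3 adjusted over the list alone; list adjusted p = 0.947). The helper NLR ADR1 rose 2.24-fold (adjusted p = 0.00272). ZAR1 and RPM1 fell 1.64-fold and 1.69-fold (adjusted p = 0.00649 and 0.0069), calls that were lost with limma on log2(TPM + 0.5) (0.0857 and 0.0754), and whose adjusted p reached 0.1 and 0.0811 over the limma settings.

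**Figure D3:**
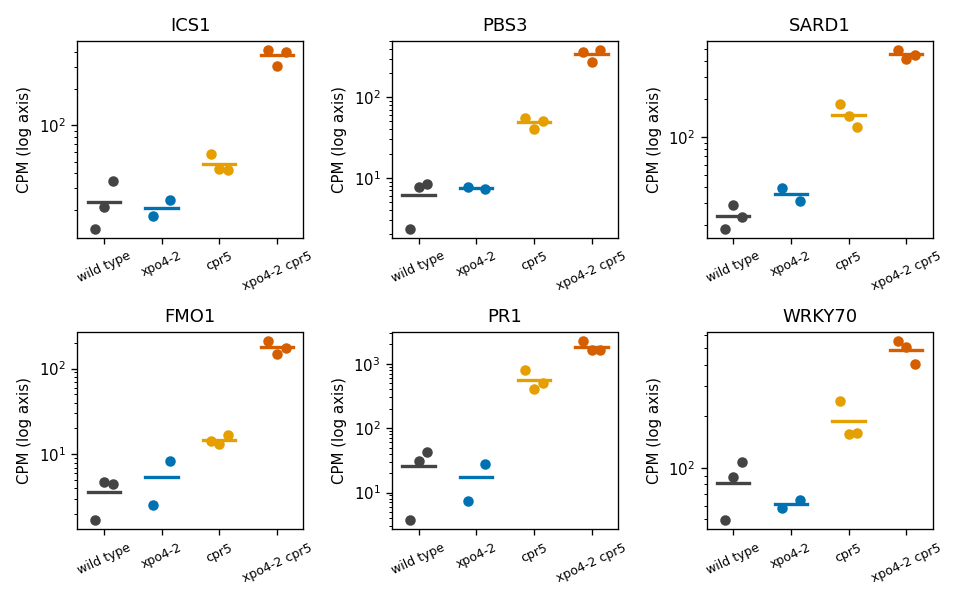
Levels of ICS1, PBS3, SARD1, FMO1, PR1 and WRKY70 (CPM, log axis) in the 4 genotypes; points are libraries and lines group means. ICS1 stands at 23.1, 20.9, 47.9 and 377 CPM in wild type, xpo4-2, cpr5 and xpo4-2 cpr5.

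The photosynthesis list had a median log2 fold change of -2.15 (20 lower adjusted over the list alone; list adjusted p = 1.98e-34, and adjusted p = 0.144 with an estimated correlation). Of the markers of other cell types, the trichome list passed, with 5 of 9 genes lower (5 adjusted over the list alone; list adjusted p = 0.0294, adjusted p = 0.179 with an estimated correlation, and 0.0767 without xpo4-2 cpr5 replicate 3). The others did not pass as lists: root and root hair had 2 of 12 higher (2 adjusted over the list alone; list adjusted p = 0.103), stomatal lineage 1 of 9 higher (0 adjusted over the list alone; list adjusted p = 0.458) and vascular tissue 2 of 7 lower (2 adjusted over the list alone; list median -0.555, list adjusted p = 0.137). Of the jasmonate and ethylene list 8 of 18 genes fell and none rose (8 adjusted over the list alone; list adjusted p = 2.75e-06, and adjusted p = 0.144 with an estimated correlation). AOS and OPR3, enzymes of jasmonate synthesis, fell 7.77-fold (585 ± 52.8 to 75.3 ± 5.4 CPM, adjusted p = 0.000157) and 6.36-fold (1070 ± 179 to 169 ± 58.4, adjusted p = 0.000263). In ER stress 5 of 11 genes rose (6 adjusted over the list alone; list adjusted p = 0.0011, and adjusted p = 0.321 with an estimated correlation), among them the chaperones SHD (1.72-fold, adjusted p = 0.0043) and BIP2 (1.96-fold, adjusted p = 0.00729). In senescence 4 of 11 rose (4 rose and 1 fell adjusted over the list alone), led by the chlorophyll-degradation gene NYE1 (2.18-fold, adjusted p = 0.00297) and the transcription factor ORE1 (6.73-fold, 15.5 ± 4.45 to 105 ± 17.2 CPM, adjusted p = 0.00375). The senescence list passed (adjusted p = 0.0281, and adjusted p = 0.321 with an estimated correlation), but not without xpo4-2 cpr5 replicate 3 (adjusted p = 0.0767) or with limma on log2(TPM + 0.5) without a filter (0.0768). DND1, a cyclic nucleotide-gated channel whose loss activates defence, fell 3.70-fold, from 170 ± 23.8 to 45.9 ± 8.27 CPM (adjusted p = 0.000176). COR15A, a cold-response gene, fell 20.4-fold (adjusted p = 0.000258).

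**Figure D4:**
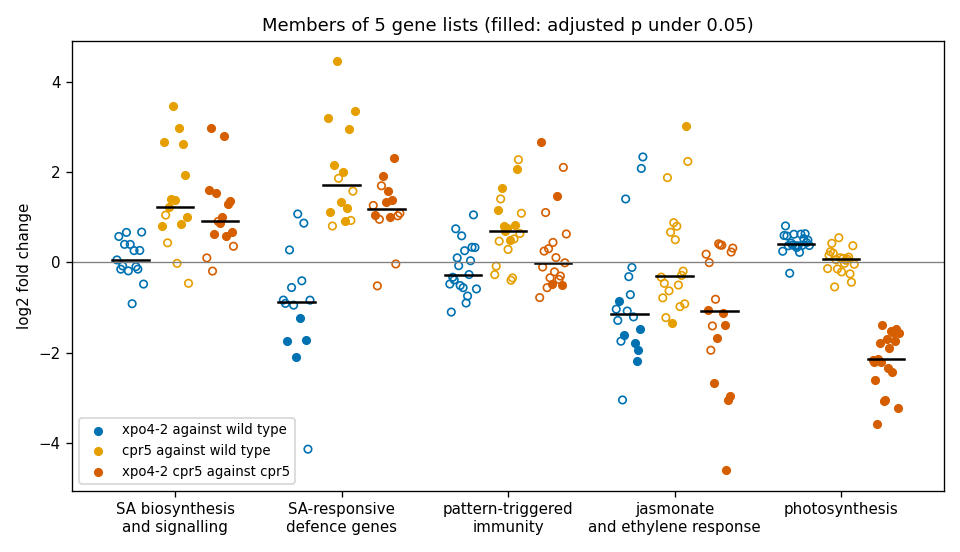
Log2 fold change of each member of 5 gene lists in xpo4-2 against wild type, cpr5 against wild type and xpo4-2 cpr5 against cpr5; filled points have an adjusted p under 0.05 and bars are list medians. The photosynthesis median is 0.41, 0.07 and -2.15 in the 3 comparisons.

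Among the largest changes against cpr5, AT4G02720 had no count in any library of the other genotypes and was at least 509-fold higher in the double mutant (28 ± 1.24 CPM). Here too, reads given to another transcript cannot be told apart from a difference of genotype. EXO70G1, an exocyst subunit, was at least 309-fold higher, but it also switched within a genotype, at 0 and 13.5 CPM in the xpo4-2 libraries. AT2G43535 was at least 233-fold higher. AT1G67105 rose 69.5-fold (adjusted p = 0.00667), with 79.6 ± 80.5 CPM in wild type, and the thioredoxin TH8 rose 69.1-fold (0.228 ± 0.2 to 16.6 ± 2.71 CPM, adjusted p = 0.000493). The metal transporter NRAMP6 was at least 139-fold lower, and likewise stood at 4.89 and 0 CPM in the xpo4-2 libraries. AT3G46370 stood at 5.04 CPM in cpr5 and 0.0169 in the double mutant. DOT3 fell 52.8-fold (adjusted p = 0.0016), CYP82G1, which makes a volatile terpene, fell 45.7-fold (57.7 ± 9.24 to 1.28 ± 0.65 CPM, adjusted p = 0.00022), and the thionin AT1G66100 fell 40.9-fold (103 ± 14.2 to 2.50 ± 0.807, adjusted p = 4.06e-05). In all 1904 genes rose and 2778 fell. Of 79 named genes that passed, 54 did so whichever library was left out. The split between rises and falls depended on scaling: 40.7% of calls were higher with TMM and 70.4% without scaling (4247 higher, 1787 lower), which moved the median log2 fold change of all genes from 0.014 to 0.273. The higher count was 963, 852 and 1059 without cpr5 replicates 1, 2 and 3 and 1153 and 1168 without xpo4-2 cpr5 replicates 1 and 3, and the lower count was 1819 without cpr5 replicate 2.

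The double mutant against wild type shows the joint effect of both mutations. PBS3 was 55.2-fold higher than in wild type (adjusted p = 1.01e-05), SARD1 19.2-fold (adjusted p = 2.51e-06), FMO1 47.9-fold (3.66 ± 1.71 to 176 ± 29.2 CPM, adjusted p = 2.35e-05) and PR2 38.4-fold (adjusted p = 0.000124). VSP2 fell 29.5-fold (283 ± 111 to 9.59 ± 1.43 CPM, adjusted p = 6.82e-06), AOS 14.7-fold (adjusted p = 1.69e-05), DND1 9.11-fold (418 ± 82.7 to 45.9 ± 8.27, adjusted p = 6.82e-06) and COR15A 84.5-fold (adjusted p = 2.17e-05). The photosystem II gene PSBP-1 fell 4.91-fold (3190 ± 689 to 651 ± 165 CPM, adjusted p = 4.81e-05). The glutathione transferase GSTF2 rose 7.86-fold (adjusted p = 0.000346), and PAD3, the last enzyme of camalexin synthesis, rose 13.5-fold (11.5 ± 7.13 to 157 ± 28.9 CPM, adjusted p = 0.00209).

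Higher genes numbered 13 of 14 SA-responsive genes, 13 of 15 in SA biosynthesis and signalling, 3 of 3 in the N-hydroxypipecolic acid pathway, 8 of 11 in senescence and 6 of 11 in ER stress, the same counts as adjusted over the list alone. The list adjusted p were 2.85e-11, 3.65e-22, 0.00012, 0.000112 and 0.00423, and with an estimated correlation the adjusted p were 0.116, 0.0533, 0.116, 0.116 and 0.326. All 20 photosynthesis genes fell (20 adjusted over the list alone; list adjusted p = 2.33e-20, and adjusted p = 0.132 with an estimated correlation), while 7 of 12 root and root hair genes rose (8 adjusted over the list alone; list median 1.97, list adjusted p = 0.00744, and adjusted p = 0.307 with an estimated correlation). In pattern-triggered immunity 10 of 19 genes rose and 1 fell (11 and 1 adjusted over the list alone; list adjusted p = 0.000912, and adjusted p = 0.116 with an estimated correlation), and in the jasmonate and ethylene list 3 of 18 rose and 9 fell (4 and 10 adjusted over the list alone; list adjusted p = 0.000145, and adjusted p = 0.116 with an estimated correlation). NLR immune receptors had 4 higher and 1 lower of 15 (4 and 1 adjusted over the list alone; list adjusted p = 0.0282, and adjusted p = 0.116 with an estimated correlation), a call lost without wild-type replicate 3 (adjusted p = 0.0509). CPL2 was at least 575-fold higher, AT4G02720 at least 487-fold and the glutamate receptor GLR1.4 at least 344-fold, although GLR1.4 stood at 4.91, 5.33 and 0 CPM in the cpr5 libraries. For CPL2 and AT4G02720, reads given to another transcript again cannot be told apart from a difference of genotype. AT5G42825 was at least 511-fold lower and AT1G69523 at least 148-fold lower. In all 3900 genes rose and 4111 fell. Of 86 named genes that passed, 78 did so whichever library was left out. The share of calls that were higher was 48.7% with TMM and 69.8% without scaling (6495 higher), with the median of all genes moving from 0.032 to 0.321.

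The comparison of xpo4-2 with wild type gives the effect of the xpo4-2 mutation alone, and it had the fewest calls. NRT1.7 fell 112-fold (224 ± 41.1 to 1.97 ± 0.736 CPM, log2 SE 0.422, adjusted p = 0.00018). VSP1 and VSP2 fell 3.85-fold (110 ± 32.8 to 28.5 ± 6.56 CPM, adjusted p = 0.00799) and 4.50-fold (283 ± 111 to 63.0 ± 9.72, adjusted p = 0.00989). WRKY54, a defence transcription factor, fell 4.28-fold (13.3 ± 5.37 to 3.13 ± 0.53 CPM, adjusted p = 0.0204), whereas it rose in the double mutant against cpr5 (2.51-fold, adjusted p = 0.00916). ICS1 stood at 23.1 ± 10.3 CPM in wild type and 20.9 ± 4.59 in xpo4-2, and none of the 15 SA biosynthesis and signalling genes passed (1 higher adjusted over the list alone; list adjusted p = 0.391).

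In the jasmonate and ethylene list 6 of 18 genes fell (10 lower and 1 higher adjusted over the list alone; list adjusted p = 3.17e-07, and adjusted p = 0.167 with an estimated correlation). Of the SA-responsive genes 4 of 14 fell (6 lower and 1 higher adjusted over the list alone; list adjusted p = 0.000549, and adjusted p = 0.501 with an estimated correlation). None of the 20 photosynthesis genes passed alone or adjusted over the list alone, with a list median of 0.41 (list adjusted p = 0.000549, and adjusted p = 0.73 with an estimated correlation), a call lost without wild-type replicate 3 (0.152) or xpo4-2 replicate 1 (0.107). Root and root hair genes had a median of 1.16, with 1 of 12 higher (2 adjusted over the list alone; list adjusted p = 0.0022, and adjusted p = 0.501 with an estimated correlation). In the N-hydroxypipecolic acid pathway, pattern-triggered immunity and senescence no gene passed, also adjusted over the list alone (list adjusted p = 0.49, 0.748 and 0.948), and 1 of 15 NLR immune receptors, RPP1, fell (1.58-fold, adjusted p = 0.0285; 2 higher and 3 lower adjusted over the list alone; list adjusted p = 0.529). CPL2 was at least 427-fold higher than in wild type, AT1G75945 stood at 0.02 CPM in wild type and 5.39 in xpo4-2, and AT4G33720, a protein of the PR1 family, rose 10.9-fold (3 ± 0.693 to 32.8 ± 16.1 CPM, adjusted p = 0.0011). The bound for CPL2 holds only if its reads in wild type were not given to another transcript. AT2G38790 fell 21.7-fold (30.7 ± 8.03 to 1.39 ± 0.548 CPM, adjusted p = 0.00353). Of 24 named genes that passed, 19 were lost without some library and 5, namely NRT1.7, CPL2, AT1G75945, AT4G33720 and AT2G38790, passed throughout. VSP1 was lost without xpo4-2 replicate 1 (adjusted p = 0.0548), and VSP2, WRKY54 and RPP1 reached an adjusted p of 0.0873, 0.140 and 0.149 without xpo4-2 replicate 2.

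In all, 163 genes rose and 423 fell in xpo4-2, with 4048 at an unadjusted p under 0.05. These calls used 1 dispersion estimate per gene over all groups, and cpr5 replicates differed less than those of wild type and xpo4-2. A fit of only the groups compared gave 0 and 1 and ended the call of each gene named here except NRT1.7, with an adjusted p from 0.0882 for AT2G38790 to 0.172 for WRKY54 and RPP1; DESeq2 gave 642 and 1227. The higher count was 70 without wild-type replicate 2, 42 and 12 without xpo4-2 replicates 1 and 2, 97, 63 and 74 without cpr5 replicates 1, 2 and 3 and 92 without xpo4-2 cpr5 replicate 1. The lower count was 156 without wild-type replicate 2, 76 and 44 without xpo4-2 replicates 1 and 2, and 217 and 262 without cpr5 replicates 2 and 3.

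The effect of the cpr5 mutation in the xpo4-2 background is read from the double mutant against xpo4-2. All 14 SA-responsive genes rose, among them WRKY54 (27.1-fold, log2 SE 0.41, adjusted p = 6.11e-05) and the receptor kinase WAK1 (8.46-fold, adjusted p = 0.00011). SARD1 rose 12.9-fold (adjusted p = 3.12e-05), PBS3 46.1-fold (adjusted p = 6.11e-05) and FMO1 31.6-fold (adjusted p = 0.000133). RPS2, an NLR receptor, rose 4.45-fold (11.7 ± 5.21 to 52.0 ± 5.99 CPM, adjusted p = 0.000369). RBCS3B fell 6.20-fold (8930 ± 1550 to 1440 ± 186 CPM, adjusted p = 4.64e-05), and NEET, an iron-sulfur protein, fell 60.2-fold (71.7 ± 7.65 to 1.21 ± 0.77, adjusted p = 5.36e-05).

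The SA-responsive list had 14 adjusted over the list alone (list adjusted p = 2.47e-17, and adjusted p = 0.0782 with an estimated correlation). In SA biosynthesis and signalling 13 of 15 genes rose, in pattern-triggered immunity 10 of 19, in NLR immune receptors 6 of 15, in the N-hydroxypipecolic acid pathway 3 of 3 and in senescence 8 of 11; adjusted over the list alone they were 13, 11, 6, 3 and 9. Their list adjusted p were 2.43e-20, 0.00027, 0.00662, 0.000517 and 7.94e-05, and with an estimated correlation the adjusted p were 0.0782, 0.0782, 0.0782, 0.171 and 0.13. All 20 photosynthesis genes fell (20 adjusted over the list alone; list median -2.56, list adjusted p = 3.71e-33, and adjusted p = 0.0782 with an estimated correlation), and none of the 12 root and root hair genes passed, also adjusted over the list alone (list adjusted p = 0.267). The jasmonate and ethylene list had 4 higher and 5 lower of 18 (4 and 5 adjusted over the list alone; list adjusted p = 0.208). AT4G02720 was at least 378-fold higher and ADPG1, a polygalacturonase of cell separation, at least 262-fold higher, and the auxin gene IAA6 fell 101-fold (adjusted p = 0.000316). The bound for AT4G02720 carries the limit given above. In all 2841 genes rose and 3348 fell. Of 79 named genes that passed, 58 did so whichever library was left out. Without xpo4-2 replicate 1 the counts were 1315 and 1928, and without scaling 69.2% of calls were higher (4852 and 2155), against 45.9% with TMM, with the median of all genes at 0.320 instead of 0.030.

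The interaction asks whether the xpo4-2 mutation had another effect in cpr5 than in wild type. For ICS1 the effect of xpo4-2 was 8.73-fold higher in cpr5 (log2 interaction 3.13, SE 0.442, adjusted p = 0.00361), and for WRKY54 it was 10.7-fold higher (3.42, SE 0.472, adjusted p = 0.00337). NIMIN-2, another partner of NPR1, had an interaction of 2.22 (adjusted p = 0.00658) and RPS2 of 1.78 (adjusted p = 0.0146). For LHCB3 the effect was 13.2-fold lower in cpr5 (-3.72, SE 0.451, adjusted p = 0.00216), for RBCS3B 5.20-fold lower (-2.38, adjusted p = 0.00197) and for VSP2 5.37-fold lower (-2.43, adjusted p = 0.00564). NRT1.7 had an interaction of 10.87 (SE 0.526, adjusted p = 1.41e-05): it was low in each single mutant (1.97 ± 0.736 and 11 ± 0.208 CPM) and stood at 184 ± 66.3 in the double mutant and 224 ± 41.1 in wild type.

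Of the photosynthesis genes 19 of 20 had a lower effect in cpr5 (20 adjusted over the list alone; list adjusted p = 4.72e-44, and adjusted p = 0.187 with an estimated correlation). Trichome markers passed in the same direction, with a median of -1.33 and 1 of 9 lower (3 adjusted over the list alone; list adjusted p = 0.0155, and adjusted p = 0.233 with an estimated correlation), as did vascular tissue, with a median of -1.04 and 1 of 7 lower (1 adjusted over the list alone; list adjusted p = 0.0257, and adjusted p = 0.298 with an estimated correlation). The vascular call was lost without xpo4-2 replicate 2 (0.0694) or xpo4-2 cpr5 replicate 2 (0.0597) and with limma on log2(TPM + 0.5) (0.0845) or log2(TPM + 0.1) (0.112). Of the SA-responsive genes 5 of 14 had a higher effect (9 adjusted over the list alone; list adjusted p = 2.81e-09, and adjusted p = 0.239 with an estimated correlation), and of SA biosynthesis and signalling 5 of 15 (6 adjusted over the list alone; list adjusted p = 6.1e-06, and adjusted p = 0.298 with an estimated correlation). In the N-hydroxypipecolic acid pathway FMO1 alone passed (7.91-fold, adjusted p = 0.0166, and 0.0502 without xpo4-2 replicate 1; 1 adjusted over the list alone). That list passed as a whole (adjusted p = 0.0211, and adjusted p = 0.435 with an estimated correlation), but not without wild-type replicate 3 (0.0708) or with limma on log2(TPM + 0.1) (0.142). Pattern-triggered immunity, NLR immune receptors and the jasmonate and ethylene list did not pass (list adjusted p = 0.779, 0.663 and 0.532). Their higher and lower members numbered 1 and 1, 1 and 0, and 0 and 2 (2 and 2, 1 and 0, and 1 and 3 adjusted over the list alone). In all, 691 genes had a higher and 1189 a lower effect of xpo4-2 in cpr5, and 16 of the 37 named genes passed whichever library was left out. Without scaling the counts were 1354 and 784, or 63.3% higher against 36.8% with TMM, with the median of all genes at 0.251 instead of -0.008. The higher count was 1122 without wild-type replicate 1, 211 and 400 without xpo4-2 replicates 1 and 2, 402, 272 and 339 without cpr5 replicates 1, 2 and 3, and 406 without xpo4-2 cpr5 replicate 1; the lower count was 416 without xpo4-2 replicate 1 and 766, 621 and 695 without the cpr5 replicates.

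The cpr5 mutation was compared between wild-type and xpo4-2 backgrounds, and the xpo4-2 mutation between wild-type and cpr5 backgrounds. Of the 928 genes higher and 505 lower in cpr5 against wild type, 602 and 296 were called in the same direction in the double mutant against xpo4-2, where independent calls would give 122 and 78.3, and 56 were called in opposite directions. Across 21580 genes, which are not independent replicates, the log2 fold changes had r = 0.414 (Spearman's rho 0.419). For the xpo4-2 mutation in both backgrounds, the shared calls were 49 higher and 209 lower, against 14.4 and 54.5, with 57 opposite, and r was 0.134 (rho 0.15). The number of opposite calls that independence would give was not worked out for either mutation, so 56 and 57 cannot be read as few. The r for xpo4-2 was 0.080 without wild-type replicate 1, 0.209 without wild-type replicate 3 and 0.058 without xpo4-2 replicate 2. The comparisons of cpr5 and of the double mutant with wild type share the wild-type libraries, and had r = 0.720 (rho 0.667) and a covariance of 1.06. In 20 simulations with no change, the shared libraries alone gave r from 0.496 to 0.543 and a covariance of 0.172 to 0.198, with a mean of 0.050 genes called in both. Every group was drawn with the same dispersion per gene, whereas wild type was the most spread group, so these ranges may be too low.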

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

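The test of the library labels was written before its result was seen, while the tests on genes at 0 counts and on the photosynthesis genes were chosen after theirs were seen. The interaction test called 691 genes with a higher and 1189 with a lower effect of xpo4-2 in cpr5 than in wild type, and the median log2 interaction was -2.455 for photosynthesis, 1.939 for SA-responsive defence genes and 0.877 for SA biosynthesis and signalling. NRT1.7 had a log2 interaction of 10.872 (adjusted p = 1.41e-05). AT1G67105 had a log2 interaction of 11.713 (adjusted p = 0.00658, and 0.0519 without xpo4-2 replicate 1), with 79.6 ± 80.5 CPM in wild type. TH8 had a log2 interaction of 9.302 (adjusted p = 0.00254). Among 13355 assembled transcripts, which the comparisons above do not use, 841 were higher and 510 lower in the double mutant than in wild type, and 151 higher and 118 lower than in cpr5 (limma on log2 TPM). TPM carries no scaling between libraries, and for genes it turned the balance in the double mutant towards higher, so the balance of these transcripts rests on that scale. One of them, MSTRG.3394.2, had a log2 fold change of 6.469 in the double mutant against wild type (adjusted p = 4.38e-05), and MSTRG.14442.1 one of 4.621 in cpr5 against wild type (adjusted p = 0.00062); both were chosen after their values were seen.

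The descriptions of the libraries give the cpr5 samples a code that joins the digits of the codes of xpo4-2 and the double mutant, so an exchange of the labels of cpr5 and the double mutant was weighed. If those labels were exchanged, XPO4 would be lower in the libraries titled cpr5. Its log2 fold change in the libraries titled xpo4-2 cpr5 against those titled cpr5 was -3.951 (adjusted p = 0.00715), the opposite direction, with counts of 46, 0 and 56 against 429, 354 and 459. The prediction rested on XPO4 being lower in xpo4-2 than in wild type, which had a log2 fold change of -2.87 and an adjusted p of 0.121, and the counts of 18 and 108 against 325, 355 and 446 do not overlap. The CPR5 transcript does not check the cpr5 mutation, but PR1, a marker of the SA defence known in cpr5 plants, stood at 407 to 787 CPM in cpr5 and 1630 to 2220 in the double mutant, against 3.68 to 42.6 in wild type and 7.34 to 27.6 in xpo4-2, which argues against an exchange of cpr5 with wild type or of the double mutant with xpo4-2.

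In 222 genes called in some comparison, every library of the lower group had 0 counts. A stretch of another strain's sequence around XPO4 or CPR5 would put most of them near those genes, but 4.55% (10 of 220, exact 95% interval 2.2% to 8.2%) lay within 2 Mb, against 7.52% of other genes. Over all 21580 genes tested, 511 switched between 0 and at least 50 counts among replicates of 1 genotype. By genotype they numbered 277 in wild type, 109 in xpo4-2, 65 in cpr5 and 191 in the double mutant. Of the 222 genes, 13.1% (29) also switched in this way, among them NRAMP6 and EXO70G1. Reads given to another transcript by the quantification may account for these, but the genes were picked for libraries at 0, so their share has no fair reference. This explanation and a difference of genotype cannot be told apart for the others, such as CPL2 and AT4G02720.

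The fall of the photosynthesis genes in the double mutant against cpr5 had a median log2 fold change of -2.15, in libraries whose 10 most abundant genes took a smaller share of counts. Scaling as the whole cause was set to need a median above -1 without scaling, and it was -1.892. Leaving out the factors moved the median of all genes only from 0.014 to 0.273, so the list could hardly have passed -1. The fall thus exceeded what the factors moved, but division by library totals remained, so an effect of composition was not decided. A lower share of all shoot tissue alike would lower stomatal lineage markers as much. The change of their mean log2 CPM minus that of the photosynthesis genes was instead 2.395 (95% interval over libraries 1.021 to 3.769). Some of these stomatal markers were low in cpr5, with MUTE at 0.525 and EPF2 at 1.09 CPM, against KAT1 at 13.6. Low values limit how far their mean could fall. A lower share of photosynthetic cells alone would raise the markers of all other cell types alike; trichome minus stomatal markers, tested first, changed by -1.339 (interval -4.018 to 1.341, Welch with Bonferroni over 6 pairs), and of all pairs, tested after that, vascular minus root markers changed by -1.329 (-1.764 to -0.895) and trichome minus root markers by -1.883 (-3.631 to -0.135). Vascular and trichome markers thus fell relative to root markers. A lower share of some green tissue may still account for part or all of the fall of the photosynthesis genes. That share, a shift in leaf age and a response of nuclear photosynthesis genes to the double mutation stay open and were not tested.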

How the results depend on the processing

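All alternatives reported here were planned. No named gene or list reversed, but without scaling the balance of calls turned from mostly lower to mostly higher in the double mutant, with 69.8%, 70.4% and 69.2% higher against wild type, cpr5 and xpo4-2, and 63.3% in the interaction. Among named genes, 3218 combinations of result and setting kept their side of the threshold, 243 lost the call and 2 gained it. With 1 library left out these were 3356, 504 and 1. Among lists, 462 kept their side and 79 lost the call, and with 1 library left out 568 and 37. Counts under RLE factors, without a low-count filter and with at least 1 CPM in 3 or more libraries stayed within 1.5 times. Counts are given as higher and lower. DESeq2 gave 642 and 1227 genes for xpo4-2 against wild type, 1527 and 1098 for cpr5 against wild type, and 1347 with a higher effect for the interaction; the cause was not tested. The fit of only the groups compared gave 0 and 1 for xpo4-2 against wild type, and 3127 higher for the double mutant against cpr5. For xpo4-2 it had fewer libraries behind its spread, while edgeR on all libraries gave 4048 genes at an unadjusted p under 0.05. Wild type and xpo4-2 were also the most spread groups (median absolute log2 difference between replicates 0.341 and 0.303, against 0.21 in cpr5 and 0.291 in the double mutant). All libraries shared 1 dispersion estimate per gene, so the 163 and 423 calls of that fit may rest partly on the less spread groups. The fit of cpr5 and wild type alone kept 660 and 360. The cause for xpo4-2 was not tested. An absolute log2 fold change of at least 1 left, by construction, 84 higher for xpo4-2, 580 and 188 for cpr5, and 2225 and 2376 for the double mutant, each against wild type, with 754 and 1404 for the double mutant against cpr5 and 1740 and 1942 against xpo4-2. Without scaling the double mutant had 6495 higher than wild type, 4247 and 1787 against cpr5 and 4852 and 2155 against xpo4-2, and the interaction 1354 and 784. In the same order, limma on log2(TPM + 0.5) gave 8003 and 2516, 5319 and 1682, 6002 and 1934, and 1513 and 749. With log2(TPM + 0.1) the counts were 7859 and 2477, 4914 and 1662, 5826 and 1922, and 1357 and 734. Without a filter log2(TPM + 0.5) gave 8011 and 2489, 5097 and 1621, 5853 and 1910, and 1324 and 692, with 329 lower for cpr5 against wild type. TPM carries no scaling between libraries, like the setting without scaling. The replicate number as a block gave 444 higher for the interaction, and the cause was not tested. Residuals of the 15 same-number pairs correlated at -0.0877 to 0.214, against -0.214 to 0.193 in the 30 pairs of other numbers. The highest, 0.214, was between wild-type replicate 1 and xpo4-2 replicate 1. Pairing by number was thus not seen across the groups, but with 2 or 3 libraries per group it cannot be excluded. Of 55 list calls 3 held with an estimated correlation. The fry test asks whether members change, without comparing them with other genes. In the double mutant against cpr5 its unadjusted p was 5.75e-05 for photosynthesis and 4.69e-05 for the jasmonate and ethylene list. For SA biosynthesis and signalling it was 0.000267 there. In xpo4-2 against wild type it was 0.14 for photosynthesis, 0.0575 for SA-responsive genes and 0.000942 for jasmonate and ethylene. The r for cpr5 in both backgrounds was 0.558 among genes of at least 10 CPM.

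With 1 library left out, counts ran from 12 to 225 higher and 44 to 545 lower for xpo4-2 against wild type, 357 to 1274 and 98 to 826 for cpr5 against wild type, and 3035 to 4254 and 3525 to 4192 for the double mutant against wild type. For the double mutant they ran from 852 to 2523 and 1819 to 3107 against cpr5 and 1315 to 3399 and 1928 to 3638 against xpo4-2, and for the interaction from 211 to 1122 and 416 to 1614. List calls ran from 47 to 60, the log2 fold change of XPO4 in the double mutant against cpr5 from -4.414 to -3.391, and the r across backgrounds from 0.058 to 0.209 for xpo4-2 and 0.321 to 0.46 for cpr5. A single count is at most 0.0591 CPM, and the lowest chi-square per degree of freedom between replicates was 11.7, so the spread between libraries exceeded counting error in every group.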

Other observations

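No test reported here was chosen after its result was seen, and the lists are those fixed in advance. In abscisic acid and cold response, COR15A fell 20.4-fold against cpr5 (83.3 ± 22.4 to 4.06 ± 1.83 CPM, adjusted p = 0.000258) and KIN1 6.19-fold (adjusted p = 0.00151), 2 of 7 genes (2 adjusted over the list alone; list adjusted p = 0.0389, and adjusted p = 0.321 with an estimated correlation). That list call was lost without cpr5 replicate 3 (0.0519), xpo4-2 cpr5 replicate 1 (0.0544) or 2 (0.0646) and with the replicate block (0.0508). In anthocyanin and flavonoid 3 of 7 genes fell against cpr5 (5 adjusted over the list alone; list adjusted p = 0.039, and adjusted p = 0.179 with an estimated correlation), led by DFR (6.50-fold, adjusted p = 0.0127). This call was lost without wild-type replicate 3 (0.0538), cpr5 replicate 3 (0.0558), xpo4-2 cpr5 replicate 2 (0.0646) or 3 (0.0644), with the replicate block (0.0782) and with only the groups compared (0.0854). Among trichome markers 5 of 9 fell against cpr5 (5 adjusted over the list alone; list adjusted p = 0.0294, and adjusted p = 0.179 with an estimated correlation). MYB23, a regulator of trichome branching, fell 5.26-fold (4.96 ± 0.841 to 0.939 ± 0.294 CPM, adjusted p = 0.00709) and TRY, an inhibitor of trichome formation, 7.76-fold (adjusted p = 0.0106). The trichome call was lost without xpo4-2 cpr5 replicate 3 (0.0767), with at least 1 CPM in 3 or more libraries (0.0839) and with the replicate block (0.0508). HSFA2, a heat shock factor, fell 7.79-fold (81.8 ± 2.49 to 10.5 ± 7.55 CPM, adjusted p = 0.0031), while heat shock had 1 gene higher and 1 lower of 8 (1 and 1 adjusted over the list alone; list adjusted p = 0.219).

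Other lists did not pass in the double mutant against cpr5. In nuclear transport receptors and nucleoporins 5 of 17 genes rose (5 higher and 2 lower adjusted over the list alone; list adjusted p = 0.103), led by the nucleoporin MOS3 (1.52-fold, 29.0 ± 1.18 to 44.2 ± 1.93 CPM, adjusted p = 0.00465) and the exportin HST (1.57-fold, adjusted p = 0.00819). XPO1B, another exportin, rose 2.17-fold in cpr5 against wild type (18.4 ± 2.47 to 40.0 ± 1.89 CPM, adjusted p = 0.00191). In the mitotic cell cycle 4 of 12 genes fell (4 adjusted over the list alone; list adjusted p = 0.137), led by CDKB2;1 (1.68-fold, adjusted p = 0.00968), a call lost with limma on log2(TPM + 0.5) (0.0757), and SIM/SMR cell cycle inhibitors had 1 higher and 1 lower of 4 (1 and 1 adjusted over the list alone; list adjusted p = 0.794). Camalexin and indole metabolism had 1 higher and 1 lower of 7 (2 and 1 adjusted over the list alone; list adjusted p = 0.478), with CYP79B3 down 2.02-fold (adjusted p = 0.00305). Oxidative stress and glutathione transferases had 1 higher and 2 lower of 13 (1 and 2 adjusted over the list alone; list adjusted p = 0.359), with the superoxide dismutase FSD1 down 1.92-fold (adjusted p = 0.00519, and 0.0648 with limma on log2(TPM + 0.5) without a filter). DND1 was the 1 of 8 TOPLESS corepressors and their DND targets that passed (1 lower adjusted over the list alone; list adjusted p = 0.947). Root and root hair had 2 higher of 12 (2 adjusted over the list alone; list adjusted p = 0.103), vascular tissue 2 lower of 7 (2 adjusted over the list alone; list adjusted p = 0.137), and stomatal lineage 1 higher of 9 (0 adjusted over the list alone; list adjusted p = 0.458). Of 3 seed storage genes measured, 2 were tested, and most members planned for this list were not measured. Of the 2, SESA1 fell 26.2-fold (7.99 ± 0.169 to 0.291 ± 0.17 CPM, adjusted p = 0.00017). The list had 1 lower adjusted over the list alone and a list adjusted p of 0.0864.

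Against wild type, root and root hair genes passed in the double mutant, with 7 of 12 higher (8 adjusted over the list alone; list adjusted p = 0.00744, and adjusted p = 0.307 with an estimated correlation), among them the cell wall protein LRX1 (15.6-fold, 1.59 ± 1.47 to 25.1 ± 8.7 CPM, adjusted p = 0.00431). In xpo4-2 the list passed with 1 of 12 higher (2 adjusted over the list alone; list adjusted p = 0.0022, and adjusted p = 0.501 with an estimated correlation). In abscisic acid and cold response, 1 of 7 genes fell in xpo4-2 (3 adjusted over the list alone; list adjusted p = 0.00367, and adjusted p = 0.363 with an estimated correlation), a call lost without xpo4-2 replicate 1 (0.288), and 4 of 7 in the double mutant (4 adjusted over the list alone; list adjusted p = 0.00767, and adjusted p = 0.161 with an estimated correlation). In cpr5 1 of these 7 genes fell (1 adjusted over the list alone; list adjusted p = 0.0252, and adjusted p = 0.258 with an estimated correlation), a call lost without wild-type replicate 2 (0.088) or cpr5 replicate 2 (0.0614). Nuclear transport receptors and nucleoporins passed in the double mutant against wild type, with 7 of 17 higher and 1 lower (7 and 1 adjusted over the list alone; list adjusted p = 0.0375, and adjusted p = 0.305 with an estimated correlation). This call was lost without wild-type replicate 1 (0.0618) or 3 (0.0622) or xpo4-2 cpr5 replicate 1 (0.0593) and with the replicate block (0.054). Seed storage passed there too, with SESA1 lower (170-fold, adjusted p = 6.89e-06; 1 adjusted over the list alone; list adjusted p = 0.0282, and adjusted p = 0.147 with an estimated correlation). Its call was lost without wild-type replicate 3 (0.0773), without a low-count filter (0.0611), with the replicate block (0.063) and with limma on log2(TPM + 0.5) (0.125, or 0.118 without a filter) or log2(TPM + 0.1) (0.113). ER stress passed in the double mutant against xpo4-2, with 5 of 11 higher (6 adjusted over the list alone; list adjusted p = 0.00786, and adjusted p = 0.477 with an estimated correlation).

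In the interaction the mitotic cell cycle passed with 2 of 12 lower (5 adjusted over the list alone; list adjusted p = 0.0155, and adjusted p = 0.524 with an estimated correlation), a call lost without xpo4-2 replicate 1 (0.0598). ER stress passed with 0 of 11 genes past the test, also adjusted over the list alone (list median 0.657, list adjusted p = 0.0155, and adjusted p = 0.553 with an estimated correlation), a call lost without wild-type replicate 3 (0.056) or xpo4-2 replicate 2 (0.066). Senescence passed with 1 of 11 higher (3 adjusted over the list alone; list adjusted p = 0.0427, and adjusted p = 0.524 with an estimated correlation). The senescence call was lost without wild-type replicate 3 (0.0708), xpo4-2 replicate 1 (0.0742) or 2 (0.0694), cpr5 replicate 2 (0.0691) or xpo4-2 cpr5 replicate 2 (0.0503) or 3 (0.472), without scaling (0.0949), with the replicate block (0.0664) and with limma on TPM (0.105, 0.142 and 0.175). The median, mean and test of a list differed in sign in 19 of 138 list tests, of which 0 passed (lowest list adjusted p = 0.396). These include the jasmonate and ethylene list in cpr5 against wild type (median -0.307, mean 0.129) and, in the interaction, seed storage (median and mean 0.717, test direction down).

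Other splits of the libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. In cpr5 against wild type the real split called 1433 genes and the highest other 0. The double mutant against wild type had 8011 genes and the highest other 1, and the double mutant against cpr5 had 4682 and the highest other 0. In each case 1 split, the real one, gave a count as large. The other splits mix the genotypes, so the difference between genotypes adds to the spread within groups. Their low counts are therefore no measure of what unchanged groups would give.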
